A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

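Each of the 8 spotted arrays compared, within 1 strain of Saccharomyces cerevisiae, RNA from cells grown on minimal medium with 10 mM glycine (channel 1) with RNA from cells grown on minimal medium (channel 2). Growth was at steady state to early log phase. BY4741, the parent of the yeast deletion collection, was on 2 arrays (replicates 1 and 3), and the bas1 and bas2 deletion strains were on 2 arrays each (replicates 1 and 2). The gcn4 and shm2 deletion strains were on 1 array each. Bas1 and Bas2 (the product of PHO2) are transcription factors that act as a pair on purine genes, Gcn4 is the activator of amino acid synthesis genes, and SHM2 encodes the cytosolic serine hydroxymethyltransferase. Strain groups were taken from the array titles and descriptions. The source name of bas2 replicate 1 gives BY4741 while its title and description give bas2, so it was kept in bas2 and left out in an alternative. A title of BY4741 replicate 3 also holds the name of another gene, zap1, which is in the zinc list below, and the array was kept in BY4741. The differences of zinc genes from BY4741 rest in part on that array.

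Per the labels, slides were scanned with a GenePix 4000B and spots were found and analysed with GenePix Pro 3.0. The deposited values are log2 of a channel ratio: 2 to the power of the value was a multiple of 0.001 for 100% of the values on every array (within 0.01 of that step). Background handling, spot filters, dyes, the direction of the ratio and any normalization are not given in the sources used here. No normalization was seen in the values, since the median over spots ran from -0.74 to 0.58 between arrays. The spot signals of the separate channels were not used here, so the signal over background behind a ratio is unknown, and the number of arrays limits the precision.

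The table held 12800 spots, of which 11138 carried 1 gene symbol, 0 carried several and 1662 carried none. Names were matched to the RefSeq gene table through the gene identifier for 11128 spots, and 10 spots kept the symbol of the platform annotation. The spots of a gene were averaged, which gave 5539 genes, 5510 of them with 2 spots and 29 with more. Each array was then centred on its median over genes, so all ratios are relative to the middle gene of their array. These medians ran from -0.78 to 0.65 between arrays, and centring moved all genes of an array by that amount. A gene was tested where it had a value on every array of the groups compared. No genome build is named in the sources used here, so no positions are given.

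Strain means and their differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, moderated test, two-sided) over all 8 arrays with 5 strain means and no other term. Spread between arrays was therefore shared by the strains, with at most 3 residual degrees of freedom, a prior of 2.30 degrees of freedom and a prior SD of 0.545. The gcn4 and shm2 arrays are assumed to vary like the replicated strains. Adjusted p is Benjamini-Hochberg over the genes of a comparison, with a threshold of 0.05. Nothing in the labels says that replicates came from separate cultures, so every p-value of this gene test measures the spread between these arrays. Errors are standard errors of the limma fit.

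Before the data were examined, 44 gene lists were fixed by hand, and those with at least 5 measured members were tested with camera of limma at its preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Camera compares a list with all other genes, whereas fry tests whether a list's genes move, on balance, 1 way. At the preset correlation, camera's p-values rest on the spread between the genes of a comparison. A small one, above all on a single array, therefore does not show that arrays repeat each other. The lists of one-carbon, purine, cytosolic and mitochondrial ribosomal protein, general stress and iron genes are reported for every comparison, and others where they passed at both the preset and the estimated correlation. That choice of lists to report was made after the results were seen, and the counts over all lists stand beside it. The one-carbon list holds the glycine cleavage system, serine hydroxymethyltransferases and folate enzymes. The purine list holds ADE genes, IMD2, IMD3, IMD4 and GUA1. Counts over a list are given adjusted over the list alone and over all genes.

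The rule for named genes was fixed before the data were examined. It covers every measured one-carbon and purine gene, the deleted genes and markers of the parent strain, and CHA1, SER1, SER3, SER33, AGX1 and GLY1. It adds up to 10 genes a side past the test with 1 sign on every array of a comparison. Where fewer passed, the places went to the largest means among genes of 1 sign and at least 1 in size on every array of the strain, or, for a difference, among genes whose arrays did not overlap. For a strain with 1 array it takes the 5 highest and 5 lowest ratios, and for a called list the 4 members with the largest mean in its direction.

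Alternatives fixed before the data were examined were no centring, a common median absolute deviation, 2 other rules on missing values, shared extreme values set missing, robust eBayes, only the arrays of the strains compared, a replicate block from the wording of the array titles, leaving out each array, a threshold of 0.10, a minimum size of 1, and the spot with the larger mean size left out. Chosen after seeing the data were leaving out the 2 arrays with the most empty spots, removing a loess curve (span 0.5) on coding length, array weights, the block with that curve, turning the sign of both bas1 arrays, setting spots with a deposited ratio within 0.003 of 1 missing, and setting each deleted gene missing on the arrays of its strain. Coding length was known for 99.9% of genes, and 96.9% of the lengths were multiples of 3. The gene test was tested on simulated data from the 5512 genes of BY4741. It recovered 2%, 20%, 72% and 90% of 50 genes shifted by 1, 2, 4 and 6 on the log2 scale and called 0 unchanged genes. Camera recovered 5 of 5 lists shifted by 1 and 0 others of 41. Simulated genes and arrays were drawn independently, so these counts do not show how often lists whose genes move together are called wrongly. Tables and plots used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.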

Results

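The 8 arrays measured, gene by gene, how the transcript level on minimal medium with glycine compared with that on minimal medium alone, in BY4741 (2 arrays), bas1 (2), bas2 (2), gcn4 (1) and shm2 (1). A value was present for 3168 genes on all arrays and for 5512 on both BY4741 arrays. Spots without a value numbered 99 and 80 of 12800 in BY4741 replicates 1 and 3, 71 and 5465 in bas1 replicates 1 and 2, and 45 and 2302 in bas2 replicates 1 and 2. They numbered 752 in gcn4 and 420 in shm2. Across genes, which are not independent replicates, BY4741 replicates 1 and 3 correlated with r = 0.39, the bas1 pair with r = 0.08 and the bas2 pair with r = 0.16. Higher values linked BY4741 replicate 1 to gcn4 (r = 0.64), bas1 replicate 1 to bas2 replicate 1 (r = 0.63) and bas1 replicate 2 to bas2 replicate 2 (r = 0.49). BY4741 replicate 3 and bas2 replicate 1, the array whose source name gives BY4741, correlated with r = 0.46. The SD over genes ran from 0.379 on BY4741 replicate 3 to 2.07 on bas1 replicate 2. Deposited ratios piled up at 1: on bas1 replicate 1, bas2 replicates 1 and 2, gcn4 and shm2, 168, 140, 83, 156 and 173 spots lay within 0.003 of it, against 44, 44, 25, 37 and 35 in the next 0.003. On BY4741 replicates 1 and 3 and bas1 replicate 2 these counts were 44, 76 and 24 against 41, 51 and 9. On bas1 replicate 1, bas2 replicate 1 and gcn4 every spot of 51, 34 and 47 genes lay there, among them 29, 19 and 17 cytosolic ribosomal protein genes, and on shm2 every spot of 17 genes, 0 of them such genes. The channel signals that would show saturation were not used here.

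**Figure D1:**
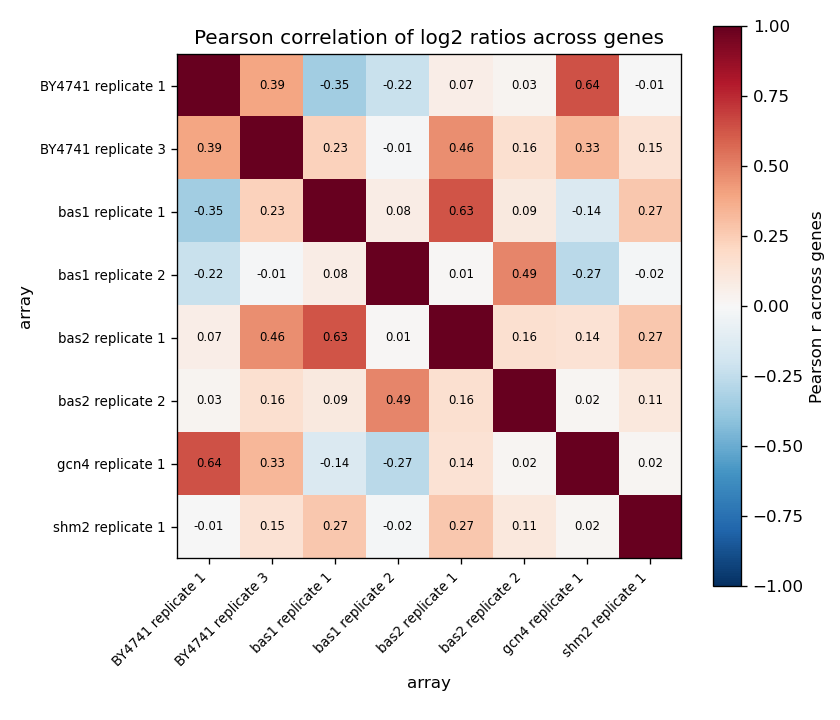
Pearson correlation of log2 ratios across genes for each pair of the 8 arrays, with the color scale from -1 to 1. The highest value outside the diagonal is 0.64 (BY4741 replicate 1 and gcn4) and the lowest is -0.35 (BY4741 replicate 1 and bas1 replicate 1).

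In BY4741, the lowest mean among genes at -1 or lower on both arrays was that of GCV1 (YDR019C), a subunit of the glycine cleavage system, at -5.77 ± 0.42 (SE, n = 2). GCV3 (YAL044C), another subunit, stood at -2.74 ± 0.28, and SHM2 (YLR058C) at -2.27 ± 0.48. A negative value is likely higher with glycine, because induction of the glycine cleavage genes by glycine is textbook knowledge and the sources used here do not state the direction. The direction is not settled for single arrays, since BY4741 replicate 1 and bas1 replicate 1 correlated at -0.304 over spots, so every sign stands as deposited. ADE3, a trifunctional folate enzyme, stood at -1.76 ± 0.50, and the purine genes ADE1 at -1.66 ± 0.58, ADE8 at -1.66 ± 0.45 and ADE17 at -1.65 ± 0.47. SNZ1, a vitamin B6 synthesis gene, stood at -4.02 ± 0.51, and SPL2, YCR101C, BSC5 and SNZ2 between -3.29 and -2.89, all below GCV3. FIT2, a cell wall mannoprotein of iron uptake, stood at 3.27 ± 0.44, PKH3 at 2.42 and TIS11, an mRNA-binding protein of the iron response, at 2.32 ± 0.31. SER3, the phosphoglycerate dehydrogenase of serine synthesis, was positive on both arrays (2.03 and 0.96).

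Among the lists in BY4741, one-carbon genes were shifted to negative ratios (19 genes, 13 negative, median -0.60, mean -0.94, camera adjusted p = 2.26e-13), and so were purine genes (13 genes, 11 negative, median -0.60, adjusted p = 9.87e-06). With an estimated correlation both had adjusted p = 0.0276. Arginine synthesis genes (7 of 8 negative, median -0.44, adjusted p = 0.0005) and general stress genes (32 of 38 negative, median -0.69, adjusted p = 3.32e-07) were shifted the same way. Positive shifts were seen for iron genes (21 of 22 positive, median 0.33, adjusted p = 2.61e-06), genes specific to a cells (6 of 7, median 0.37, adjusted p = 0.0200) and cytosolic ribosomal protein genes (117 of 133, median 0.68, adjusted p = 8.03e-18). The ribosomal protein call had adjusted p = 0.193 with an estimated correlation. Mitochondrial ribosomal protein genes (49 of 65 positive, median 0.30, adjusted p = 0.0153) had adjusted p = 0.689 with an estimated correlation. Adjusted over the list alone, 4 one-carbon, 2 arginine and 2 iron genes passed, and 0 of them passed over all genes. Of 41 lists, camera called 16 (11 negative, 5 positive), 6 with an estimated correlation. Fry, run only over genes with a value on all 8 arrays and so without GCV1 and GCV3, called 2.

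No gene passed limma's test in BY4741 (0 of 5512, 186 at an unadjusted p under 0.05, smallest adjusted p = 0.588). From the BY4741 arrays alone, GCV1 and SNZ1 passed. On both arrays, 39 genes stood at -1 or lower and 20 at 1 or higher, against 7.28 and 7.06 by chance, and without centring these counts were 13 and 52. List medians differed between replicates 1 and 3: -1.11 and -0.12 for one-carbon, -0.97 and -0.66 for purine, -0.32 and -0.53 for stress, 0.10 and 0.58 for iron, 1.05 and 0.28 for cytosolic ribosomal protein and 0.52 and 0.05 for mitochondrial ribosomal protein genes. Without replicate 3 the iron (adjusted p = 0.352), arginine (0.0640) and a-specific (median 0.67, adjusted p = 0.0794) calls ended, and without replicate 1 the mitochondrial one did (0.490), as it did with the coding-length curve removed (median 0.17, adjusted p = 0.384), while the a-specific median was 0.14. Without centring the medians were -0.12 for one-carbon, -0.11 for purine, -0.20 for stress, 0.04 for arginine, 0.82 for iron, 0.86 for a-specific, 1.17 for cytosolic and 0.79 for mitochondrial ribosomal protein genes. Scaled to a common median absolute deviation they were -0.99 for purine, -0.76 for arginine, 0.96 for iron and 0.92 for a-specific genes.

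**Figure D2:**
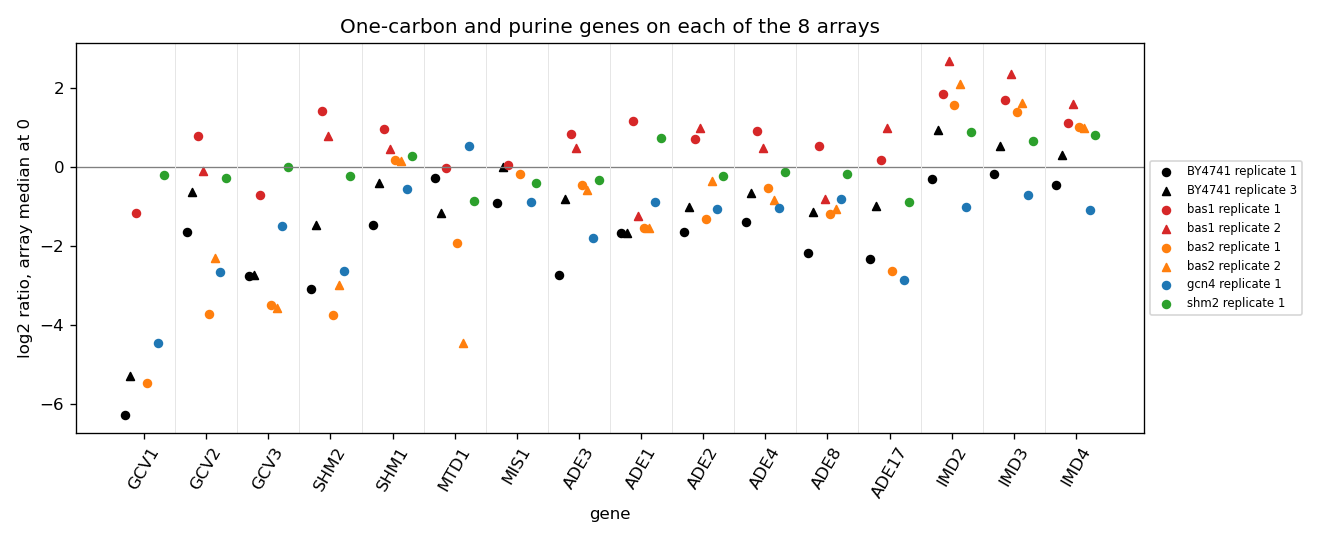
Median-centred log2 ratio (y axis) of 16 one-carbon and purine genes (x axis), with 1 point per array, color for strain, circles for replicate 1 and triangles for the other replicate. GCV1 lies at -6.27 and -5.27 in BY4741, at -5.45 in bas2 and -4.46 in gcn4, against -1.17 in bas1 and -0.20 in shm2. The SHM2 point of shm2 comes from a gene deleted there.

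In bas1, one-carbon genes went both ways. GCV1 was at -1.17 and GCV3 at -0.70 on the array that had a value, and SHM2 was at 1.10 ± 0.48 (n = 2), with 1.41 and 0.79 on the arrays. IMD2, IMD3 and IMD4, which encode the first enzyme of guanine nucleotide synthesis, stood at 2.26 ± 0.43, 2.02 ± 0.33 and 1.35 ± 0.32. The highest means were those of PRM2 (4.68), FIT2 (4.64 ± 0.44), ZPS1, a zinc-regulated cell wall protein (3.92 ± 0.87), and POG1 (3.78). POG1 stood at 1.25 and 6.30 on the arrays. TIS11 stood at 3.47 ± 0.31 and ZRT2, a zinc transporter, at 2.01 ± 0.40. The lowest were those of PBI2 (-4.00), KAR1 and TMA23 (both -3.88) and HSP26, a small heat shock protein (-3.71 ± 0.61).

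The one-carbon list, of which 13 genes without GCV1 and GCV3 had a value on both arrays, was not called in bas1 (8 positive, median 0.10, adjusted p = 0.667), and the cytosolic ribosomal protein list was not called either (median 0.06, adjusted p = 0.886). Without centring these medians were -0.18 and -0.22. Purine genes were shifted to positive ratios (9 of 12 positive, median 0.71, camera adjusted p = 0.00169), with adjusted p = 0.0944 with an estimated correlation. Iron genes (11 of 13 positive, median 1.99, adjusted p = 1.10e-09), zinc genes (10 of 11, median 1.28, 0.000508), ergosterol genes (16 of 19, median 0.79, 0.00273), lysine synthesis genes (8 of 8, median 0.75, 0.00812) and phosphate genes (9 of 13, median 0.64, 0.0175) were shifted the same way. Stress genes were shifted to negative ratios (17 of 22 negative, median -0.82, adjusted p = 2.43e-05). Mitochondrial ribosomal protein genes (26 of 32 negative, median -0.53, adjusted p = 3.04e-06) had adjusted p = 0.0973 with an estimated correlation. Adjusted over the list alone, 7 iron, 3 purine, 3 zinc, 2 lysine, 2 phosphate, 4 mitochondrial ribosomal protein and 1 stress genes passed, and 0 over all genes. Camera called 18 of 36 lists (3 negative, 15 positive), 6 with an estimated correlation, and fry called 15.

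No gene passed limma's test in bas1 (0 of 3444, 583 at an unadjusted p under 0.05), and TIS11 had the smallest adjusted p, 0.159. Without centring FIT2 passed, and without bas1 replicate 2 and bas2 replicate 2 YLR030W did. Leaving out bas1 replicate 1 left a lone array with the widest spread, on which 641 genes passed (334 negative, 307 positive). Lists called fell from 18 to 3, and the purine (median 0.95, adjusted p = 0.525), stress (0.522), zinc (0.156), lysine (0.525), ergosterol (0.609) and phosphate (0.39, 0.623) calls ended. Without bas1 replicate 2 the lysine and ergosterol medians were 0.44 and 0.49, and without either bas2 replicate the phosphate call ended (0.0564). Without centring the lysine (0.112), phosphate (0.316) and ergosterol (0.158) calls ended, and the purine and mitochondrial ribosomal protein medians were 0.43 and -0.81. With the coding-length curve removed the purine median was 0.47, and with a common median absolute deviation the ergosterol median was 0.52. On both arrays 112 genes stood at -1 or lower and 127 at 1 or higher, against 49.5 and 71.5 by chance, with 109 and 62 without centring. With the sign of both bas1 arrays turned, chosen after seeing the data, all bas1 medians changed sign, so that the purine median was -0.71, the iron median -1.99 and the stress median 0.82.

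In bas2, several one-carbon genes had low ratios, and the lowest mean was that of FLO9 (-4.03). GCV3 stood at -3.52 ± 0.28 (n = 2), SHM2 at -3.36 ± 0.48, MTD1, a cytosolic methylenetetrahydrofolate dehydrogenase, at -3.19 ± 0.70 and GCV2 at -3.00 ± 0.50. GCV1 was at -5.45 on replicate 1, the array that had a value. SHM1, the mitochondrial serine hydroxymethyltransferase, stood at 0.16 and LPD1, the subunit that the cleavage system shares with other enzymes, at -0.45. The purine genes went both ways: ADE17 was at -2.62 on replicate 1 and ADE1 at -1.54 on average, while IMD2 stood at 1.84 and IMD3 at 1.51. FIT2 stood at 4.30 ± 0.44, ZPS1 at 3.55 ± 0.87, FIT1 at 3.44 and ZRT1, the high-affinity zinc transporter, at 2.84 ± 1.02. Stress genes included MSC1 at -3.59 ± 0.87 and DCS2 at -3.10 ± 0.53, and BAR1, a protease secreted by a cells, stood at 1.70 ± 0.32.

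The one-carbon list was shifted to negative ratios in bas2 (11 of 17 negative, median -0.35, mean -0.87, camera adjusted p = 3.19e-07), with adjusted p = 0.0744 with an estimated correlation. The purine list was not (6 of 12 negative, median -0.26, mean 0.01, adjusted p = 0.968). Stress genes (26 of 28 negative, median -1.22, adjusted p = 3.55e-18), arginine genes (median -0.62, 0.0165) and oxidative stress genes (median -0.27, 0.0370) were also shifted negative. Iron (17 of 19 positive, median 1.13, adjusted p = 1.07e-17), a-specific (7 of 7, median 1.26, 3.99e-08), mating response (median 0.59, 4.13e-05), zinc (median 0.75, 9.11e-05), ergosterol (median 0.46, 0.00148) and lysine genes (median 0.58, 0.00967) were shifted positive. Genes specific to alpha cells, silent in an a strain, also stood above the middle, with medians of 1.04 (4 genes) and 0.98 (1 gene) on the bas2 arrays, so the a-specific and mating calls are not separated from a drift of silent genes. Cytosolic ribosomal protein genes (median 0.33, adjusted p = 2.00e-06) had adjusted p = 0.508 with an estimated correlation, and mitochondrial ones (median -0.36, adjusted p = 9.11e-05) had adjusted p = 0.319 with an estimated correlation. Adjusted over the list alone, 8 stress, 5 iron, 4 a-specific, 4 one-carbon, 3 purine, 3 zinc and 1 oxidative stress genes passed, and 0 over all genes. Camera called 21 of 40 lists (10 negative, 11 positive), 9 with an estimated correlation, and fry called 9.

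No gene passed limma's test in bas2 (0 of 4897, 272 at an unadjusted p under 0.05, smallest adjusted p = 0.379), and 0 passed under the other settings tried. Without bas2 replicate 1, the array with conflicting labels, 11 lists were called, and the zinc (adjusted p = 0.0742), mating (0.0742), ergosterol (0.108), arginine (0.0838), oxidative (median -0.58, 0.175) and mitochondrial ribosomal protein (0.283) calls ended, while the cytosolic median was 0.64. Without bas2 replicate 2 the cytosolic ribosomal protein (median 0.03, adjusted p = 0.397), lysine (0.25, 0.0888), arginine (-0.10, 0.171) and oxidative (-0.10, 0.337) calls ended and the one-carbon median was -0.18. Without either BY4741 replicate the oxidative call ended (0.0646), and with a common median absolute deviation the arginine call ended (0.0611). On both arrays 65 genes stood at -1 or lower and 60 at 1 or higher, against 24.0 and 17.7 by chance, with 43 and 42 without centring.

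On the single gcn4 array, GCV1 stood at -4.46, GCV2 at -2.65, SHM2 at -2.63 and GCV3 at -1.50, and the purine gene ADE17 at -2.86. MET17, a sulfur assimilation gene absent from the parent's genotype, stood at -2.80. The lowest ratios were those of BSC1 (-7.70), ERC1 (-7.38), MEI4 (-7.38), YIL171W (-7.25) and CTF19 (-6.90), and the highest those of MMT1 (6.09), VEL1 (3.87), CRM1 (3.51), YOR387C (3.48) and PUS7 (3.45). Of these 10 genes, 7 rested on 1 spot with a value. The purine list was shifted negative (13 genes, median -0.88, camera adjusted p = 0.0340), with adjusted p = 0.479 with an estimated correlation. Cytosolic (126 of 133 positive, median 0.88, adjusted p = 2.23e-11) and mitochondrial ribosomal protein genes (54 of 64 positive, median 0.87, adjusted p = 4.29e-06) were shifted positive. They had adjusted p = 0.581 and adjusted p = 0.479 with an estimated correlation. The one-carbon (median -0.56, adjusted p = 0.0765), stress (median -0.37, adjusted p = 0.211) and iron lists (median -0.56, adjusted p = 0.784) were not called.

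Camera called 10 of 41 lists in gcn4 (7 negative, 3 positive), 0 with an estimated correlation, and fry called 1. Of 5378 genes, 0 passed limma's test (616 at an unadjusted p under 0.05, smallest adjusted p = 0.180), and adjusted over each reported list alone 0 passed. The purine call ended without bas1 replicate 1 or 2 (adjusted p = 0.0544), without bas2 replicate 1 or 2 (0.0506) with the coding-length curve removed (0.0796) and with a common median absolute deviation (median -0.60, adjusted p = 0.0635), and the one-carbon call was gained without BY4741 replicate 1 or 3 (0.0311). With that curve removed the cytosolic and mitochondrial ribosomal protein medians were 0.50 and 0.46. Without centring 13 genes passed, and 4 (BSC1, CTF19, PRR2 and ECM18) passed without either bas1 array. Without bas1 replicate 2 and bas2 replicate 2, 122 genes passed (114 negative, 8 positive), with a spread that then rested on the BY4741 pair alone.

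On the single shm2 array, one-carbon genes with low ratios in BY4741 stood close to the middle: GCV1 at -0.20, GCV2 at -0.27 and GCV3 at -0.01. Stress genes were low, with DDR2 at -4.25, GPH1, glycogen phosphorylase, at -3.88, HSP12 at -3.37 and GLK1, glucokinase, at -3.01. Other genes at the lower end were ATG7 and HAL5 (both -4.51), PET18 (-4.25) and ECM2 (-4.23), and at the upper end HXT17 (4.89), HSP32 (3.81), ROK1 (3.74), TAO3 (3.52) and SQT1 (3.47). Of the 5 highest and 5 lowest genes, 8 rested on 1 spot with a value. The stress list was shifted negative (34 of 37 negative, median -1.47, camera adjusted p = 1.76e-19). The cytosolic ribosomal protein list was shifted positive (123 of 133 positive, median 0.60, adjusted p = 2.85e-12), with adjusted p = 0.705 with an estimated correlation. The one-carbon (median -0.24, adjusted p = 0.783), purine (median -0.12, mean 0.25, adjusted p = 0.613), iron (median 0.58, adjusted p = 0.139) and mitochondrial ribosomal protein lists (median -0.26, adjusted p = 0.0745) were not called.

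Camera called 5 of 41 lists in shm2 (3 negative, 2 positive), 1 with an estimated correlation, and fry called 1. Of 5469 genes, 0 passed limma's test (258 at an unadjusted p under 0.05, smallest adjusted p = 0.703) and 0 passed under the other settings. The mitochondrial ribosomal protein list was called without BY4741 replicate 1 or 3 (0.0499). Adjusted over the list alone 2 stress genes passed, and 0 over all genes.

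Averaged over the 5 strains with equal weight, TIS11 stood at 2.19 ± 0.16 (8 of 8 arrays positive) and YGL039W at 1.28 ± 0.14. These were the genes with 1 sign and at least 1 in size on every array. GAD1, glutamate decarboxylase, stood at -1.76 ± 0.22 and PGM2, phosphoglucomutase, at -1.32 ± 0.15. All 21 stress genes were negative on average (median -0.91, camera adjusted p = 1.19e-21), and 14 of them passed adjusted over the list alone, 0 over all genes. So did 5 iron, 3 purine, 3 zinc, 3 a-specific, 2 one-carbon (SHM2, which the shm2 strain lacks, and GCV2) and 1 ergosterol genes. Iron (11 of 12 positive, median 0.72, adjusted p = 5.44e-10), zinc (median 0.72, 0.000493), a-specific (median 0.67, 0.000311) and ergosterol genes (median 0.24, 0.0232) were shifted positive. Cytosolic ribosomal protein genes (127 of 130 positive, median 0.54, adjusted p = 2.83e-20) had adjusted p = 0.149 with an estimated correlation. One-carbon genes (median -0.07, adjusted p = 0.0198) had adjusted p = 0.409 with an estimated correlation, while purine (median -0.16, adjusted p = 0.450) and mitochondrial ribosomal protein genes (median -0.12, adjusted p = 0.0619) were not called.

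For this average, camera called 13 of 36 lists (7 negative, 6 positive), 5 with an estimated correlation, and fry called 8. Of 3168 genes, 0 passed limma's test (521 at an unadjusted p under 0.05), and the smallest adjusted p was 0.0813, for TIS11. TIS11 passed with the spot of larger mean size left out or at a threshold of 0.10, TIS11 and FIT2 passed without centring, and 97 genes (87 negative, 10 positive) passed without bas1 replicate 2 and bas2 replicate 2. The one-carbon call ended without bas1 replicate 1 (median -0.15, adjusted p = 0.0909), and with each deleted gene set missing on the arrays of its strain, which takes SHM2 out (median -0.05, adjusted p = 0.0800). Its median ran from -0.24 without gcn4 to -0.03 without BY4741 replicate 1, and was -0.17 without BY4741 replicate 3, -0.19 without bas1 replicate 2, -0.12 without bas2 replicate 1 and -0.15 without shm2. The zinc call ended without BY4741 replicate 3 (0.106), and the ergosterol call ended without BY4741 replicate 3 (0.0842), bas1 replicate 1 (0.0667) or shm2 (0.0567) and without centring (0.0699), with a median of 0.38 without gcn4. The mitochondrial list passed without BY4741 replicate 1 (0.0395), bas1 replicate 1 (0.0411) or gcn4 (median -0.29, adjusted p = 2.28e-05), with the coding-length curve removed (median -0.21, adjusted p = 0.00508) and with a common median absolute deviation (0.0109). With that curve removed the one-carbon median was -0.13, and without centring -0.12. With the sign of both bas1 arrays turned the iron (median 0.18, adjusted p = 0.255), zinc (0.22, 0.485) and ergosterol (-0.04, 0.981) calls ended, the purine list was called (-0.44, 0.000487), and the medians were 0.25 for mitochondrial ribosomal protein (0.0798), 0.38 for a-specific, -0.54 for stress and -0.18 for one-carbon genes.

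**Figure D3:**
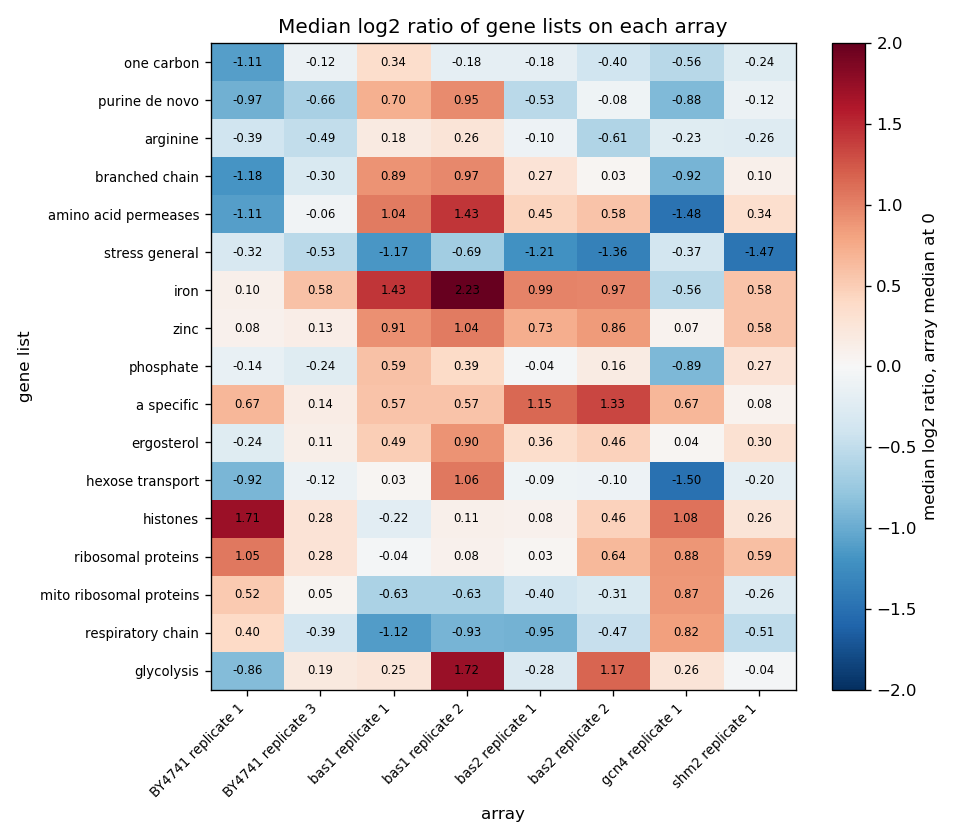
Median log2 ratio of 17 gene lists (y axis) on each of the 8 arrays (x axis), with the median of each array at 0 and color from -2.0 to 2.0. The stress list is negative on every array, from -0.32 to -1.47, and the iron list runs from -0.56 on gcn4 to 2.23 on bas1 replicate 2.

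The comparison of bas1 with BY4741 asks which glycine responses differed without Bas1. SHM2 stood 3.37 ± 0.68 above its BY4741 ratio, ADE3 2.42 ± 0.70 and MET6, methionine synthase, 2.30 ± 0.42. Purine genes differed together: all 12 lay above BY4741 (median 1.57, camera adjusted p = 5.99e-06; adjusted p = 0.0157 with an estimated correlation), with ADE17 at 2.23 ± 0.67, ADE2 at 2.17 ± 0.51 and IMD2 at 1.96 ± 0.61. The largest differences were those of ENT4 (5.49), BSC5 (5.17) and PRM2 (5.03) above and TMA23 (-5.41), PBI2 (-5.21) and KAR1 (-4.97) below BY4741. On bas1 replicate 1 ENT4 and BSC5 stood at 0.68 and -0.16, and on replicate 2 BSC5 stood at 4.51. One-carbon genes also lay higher (9 of 13, median 0.47, adjusted p = 0.0236), with adjusted p = 0.398 with an estimated correlation. Zinc (median 1.57, adjusted p = 0.00711), phosphate (1.15, 0.00711), lysine (1.14, 0.0187), arginine (0.99, 0.00855) and ergosterol genes (0.88, 0.0179) lay higher. Iron genes (median 1.37, adjusted p = 0.0187) had adjusted p = 0.236 with an estimated correlation. Cytosolic (median -0.63, adjusted p = 3.84e-05) and mitochondrial ribosomal protein genes (median -0.74, adjusted p = 3.84e-05) lay lower, with adjusted p = 0.398 and adjusted p = 0.200 with an estimated correlation. The stress list was not called (median -0.22, adjusted p = 0.273).

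Within the pairs of arrays that share a title wording (replicates 1, then replicates 3 and 2), the median of bas1 minus BY4741 was 2.15 and 1.22 for purine, 1.52 and -0.10 for one-carbon, 1.26 and 0.98 for iron, 0.97 and 0.91 for zinc, -0.99 and -0.20 for cytosolic ribosomal protein, -1.17 and -0.63 for mitochondrial ribosomal protein and -1.004 and -0.34 for stress genes. The purine shift was not particular to purine genes. These medians were 2.07 and 1.22 for branched-chain amino acid, 1.29 and 1.58 for glycolysis and 1.38 and 1.12 for hexose transporter genes. Other lists lay closer to BY4741 or below it. Camera called 22 of 36 lists (5 negative, 17 positive), 6 with an estimated correlation, and fry called 3. Adjusted over the list alone, 4 phosphate, 3 purine, 2 one-carbon, 1 arginine and 1 iron genes passed, and 0 over all genes. Of 3429 genes, 0 passed limma's test (494 at an unadjusted p under 0.05, smallest adjusted p = 0.338). Without bas1 replicate 1, 493 genes passed on the lone second array and 2 lists were called. The purine (adjusted p = 0.134), one-carbon (median -0.04, 0.794), zinc (0.173), phosphate (0.488), lysine (0.481), arginine (0.443), ergosterol (0.499), iron (0.208) and cytosolic ribosomal protein (0.208) calls ended. Without bas1 replicate 2 the one-carbon median was 1.02, zinc 0.92, phosphate 0.62 and arginine 0.59, the stress list was called (-0.76, adjusted p = 0.00295), and without the second bas1 and bas2 arrays YLR030W passed.

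The same difference also moved with the BY4741 array used. Without BY4741 replicate 1 the medians were 0.18 for one-carbon, 0.71 for iron, 0.91 for zinc and -0.22 for cytosolic ribosomal protein genes. Without BY4741 replicate 3 they were 0.97 for one-carbon and -1.04 for cytosolic ribosomal protein genes, and the arginine (adjusted p = 0.0567), phosphate (0.104) and ergosterol (0.0698) calls ended. With a common median absolute deviation the iron median was -0.07 (adjusted p = 0.592), the stress median 0.42, the zinc median 0.93, and the lysine (0.0910) and ergosterol (0.182) calls ended. Without centring the one-carbon median was -0.30 (adjusted p = 0.110), and the arginine (0.189), lysine (0.142), phosphate (0.0957), iron (0.0570) and ergosterol (0.278) calls ended. The purine, zinc, cytosolic and mitochondrial ribosomal protein medians were then 0.80, 0.80, -1.39 and -1.50. With the coding-length curve removed the ergosterol call ended (0.0662) and the cytosolic ribosomal protein median was -0.31. With the sign of both bas1 arrays turned, the purine (median 0.11, adjusted p = 0.856), one-carbon (0.26, 0.122), arginine (0.29, 0.176), phosphate (-0.16, 0.346) and lysine (-1.10, 0.0513) calls ended. The iron, zinc, ergosterol and mitochondrial ribosomal protein medians were then -2.35, -1.30, -0.80 and 0.48, and the stress list was called (1.26, 1.57e-11).

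Between bas2 and BY4741, one-carbon genes did not differ as a list (median -0.17, camera adjusted p = 0.763), while purine genes lay higher in bas2 (median 0.59, adjusted p = 0.00182; adjusted p = 0.112 with an estimated correlation). IMD2 stood 1.54 ± 0.61 and IMD3 1.33 ± 0.47 above their BY4741 ratios. The largest differences were those of YCR101C (4.65), SPL2 (3.95) and PIR5 (3.91) above and CGR1 (-3.33), RRP14 (-3.28) and PKH3 (-3.22) below BY4741. Those above rested mostly on bas2 replicate 2. On replicates 1 and 2 YCR101C stood at -0.68 and 3.74, SPL2 at -2.15 and 3.48 and PIR5 at 0.18 and 4.73. Stress genes lay lower (median -0.65, adjusted p = 0.000591), with PNC1, a nicotinamidase, at -2.48 ± 0.68 and DCS2 at -2.30 ± 0.75. Mating response (median 0.82, adjusted p = 0.00114), zinc (0.88, 0.00232), ergosterol (0.49, 0.00357), a-specific (0.52, 0.00479) and lysine genes (0.76, 0.00510) lay higher, among them ZPS1 at 3.43 ± 1.23 and BAR1 at 1.33 ± 0.45. Iron genes (median 0.83, adjusted p = 0.00149) had adjusted p = 0.146 with an estimated correlation. Mitochondrial (median -0.59, adjusted p = 6.29e-07) and cytosolic ribosomal protein genes (median -0.33, adjusted p = 0.0455) lay lower, with adjusted p = 0.158 and adjusted p = 0.757 with an estimated correlation.

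Within title wordings, the median of bas2 minus BY4741 was 0.86 and 0.26 for purine, -0.16 and -0.22 for one-carbon, 0.88 and 0.28 for iron, -1.04 and -0.66 for stress, -0.83 and -0.37 for mitochondrial ribosomal protein and -0.93 and 0.31 for cytosolic ribosomal protein genes, so the last did not hold within both. Here too the purine shift was not particular, with 1.43 and 0.24 for branched-chain amino acid and 1.60 and 0.51 for amino acid permease genes. Camera called 22 of 40 lists (6 negative, 16 positive), 6 with an estimated correlation, and fry called 2. Of 4874 genes, 0 passed limma's test (90 at an unadjusted p under 0.05, smallest adjusted p = 0.846) and 0 passed under the other settings, and adjusted over each reported list alone 0 passed. Without bas2 replicate 1, 7 lists were called, and the stress (median -0.40, adjusted p = 0.153), zinc (0.128), mating (0.128), ergosterol (0.30, 0.128), a-specific (0.150), iron (0.128), mitochondrial (0.0568) and cytosolic ribosomal protein (-0.04, 0.414) calls ended. Without bas2 replicate 2 the purine (0.103) and lysine (0.0870) calls ended, the iron median was 0.55 and the cytosolic ribosomal protein median -0.58.

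Without BY4741 replicate 1 the purine (median 0.13, adjusted p = 0.0586), iron (0.24, 0.0586) and cytosolic ribosomal protein (0.05, 0.192) calls of bas2 minus BY4741 ended, and the lysine and mating medians were 0.45 and 0.49. Without BY4741 replicate 3 the stress (0.163) and a-specific (0.200) calls ended, and the purine and cytosolic ribosomal protein medians were 1.13 and -0.62. Without either bas1 array the cytosolic ribosomal protein call ended (0.0849), as it did with the coding-length curve removed (0.354) and with spots near a ratio of 1 set missing (median -0.22, adjusted p = 0.257). With a common median absolute deviation the iron median was -0.04 (adjusted p = 0.462). Without centring the ergosterol (-0.07, adjusted p = 0.0605) and a-specific (-0.04, 0.0597) medians turned, and the medians were 0.033 for purine, 0.28 for iron, 0.33 for zinc, 0.20 for lysine, 0.27 for mating, -1.20 for stress, -0.88 for cytosolic and -1.14 for mitochondrial ribosomal protein genes.

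For the mean of bas1 and bas2, whose products act as a factor pair, against BY4741, all 11 purine genes lay above BY4741 (median 1.02, camera adjusted p = 0.000118; adjusted p = 0.0369 with an estimated correlation). IMD2 stood at 1.75 ± 0.53, IMD3 at 1.59 ± 0.41 and ADE2 at 1.34 ± 0.44. YCR101C (4.73), PIR5 (4.25) and ENT4 (4.06) lay furthest above and PBI2 (-3.75), RRP36 (-3.33) and CUP1-1 (-3.15) furthest below BY4741. On the first bas1 and bas2 arrays YCR101C stood at -0.48 and -0.68 and PIR5 at 1.11 and 0.18. On the second arrays YCR101C stood at 3.83 and 3.74 and PIR5 at 5.15 and 4.73. A mean does not show what the strains share: in bas2 alone ADE12 (-1.33, against -0.81 in BY4741) and ADE13 (-0.57, against -0.50) lay below BY4741. Zinc (median 1.14, adjusted p = 0.000868), lysine (1.13, 0.0114), phosphate (1.10, 0.00910) and ergosterol genes (0.87, 0.00864) also lay higher, and stress genes lower (-0.56, 0.0244). Iron genes (median 1.17, adjusted p = 0.00969) had adjusted p = 0.140 with an estimated correlation. Cytosolic (median -0.48, adjusted p = 4.92e-05) and mitochondrial ribosomal protein genes (median -0.58, adjusted p = 3.46e-05) had adjusted p = 0.490 and adjusted p = 0.135 with an estimated correlation. The one-carbon list was not called (median 0.32, adjusted p = 0.138; -0.34 without centring). Camera called 22 of 36 lists (5 negative, 17 positive), 6 with an estimated correlation, and fry called 3.

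No gene passed limma's test for this mean (0 of 3245, 311 at an unadjusted p under 0.05, smallest adjusted p = 0.469) and 0 passed under the other settings, and adjusted over the list alone 1 iron gene passed. The replicate differences of bas1 and bas2 correlated across genes (r = 0.542), which this fit ignores, so the errors for the mean may be too small. Without bas1 replicate 1, 8 lists were called, and the lysine (adjusted p = 0.0870), ergosterol (0.0870), phosphate (0.0984), iron (0.0823), stress (0.209) and cytosolic ribosomal protein (0.101) calls ended. Without BY4741 replicate 3 the stress (-0.26, 0.635), phosphate (0.213), lysine (0.0515) and ergosterol (0.0727) calls ended, and the purine, zinc and cytosolic ribosomal protein medians were 1.59, 1.74 and -0.80. Without BY4741 replicate 1 the iron, ergosterol and cytosolic ribosomal protein medians were 0.55, 0.56 and -0.08. Without bas1 replicate 2 the ergosterol median was 0.56 and the one-carbon list was called (0.0309), and without bas2 replicate 2 the stress median was -0.27. With a common median absolute deviation the iron median was -0.17 (0.698), and the stress (0.694) and ergosterol (0.0759) calls ended, the latter also without centring (0.143). Without centring the medians were 0.36 for purine, 0.51 for iron, 0.47 for lysine and zinc, 0.43 for phosphate, -1.22 for stress, -1.14 for cytosolic and -1.24 for mitochondrial ribosomal protein genes. With the coding-length curve removed the cytosolic ribosomal protein median was -0.18, and with spots near a ratio of 1 set missing -0.23. With the sign of both bas1 arrays turned the purine (median 0.15, adjusted p = 0.612) and phosphate (0.13, 0.858) calls ended, as did those of lysine (0.780), zinc (0.728), ergosterol (0.621) and mitochondrial ribosomal protein genes (0.613), and the iron and stress medians were -0.75 and 0.44.

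Between gcn4 and BY4741, GCV1 and SHM2 were low in both, and the one-carbon (median 0.21, camera adjusted p = 0.192), purine (median -0.01, adjusted p = 0.928) and stress lists (median 0.24, adjusted p = 0.516) were not called. MEI4 (-7.07), YIL171W (-6.88) and CTF19 (-6.60) lay furthest below and MMT1 (5.95), VEL1 (4.28) and YOR387C (3.89) furthest above BY4741 in gcn4. Iron genes lay lower in gcn4 (21 of 22, median -0.87, adjusted p = 0.000932), with the siderophore transporters ARN1 and ENB1 at -2.17 ± 1.15 and -1.94 ± 0.82. The spots of FIT2 lay within 0.003 of a ratio of 1 on gcn4, where abundant genes piled up, so no difference is given for it. That list had adjusted p = 0.535 with an estimated correlation. Mitochondrial (median 0.47, adjusted p = 4.35e-05) and cytosolic ribosomal protein genes (median 0.29, adjusted p = 0.00427) lay higher, with adjusted p = 0.777 and adjusted p = 0.963 with an estimated correlation. Without centring their medians were -0.27 and -0.46, the one-carbon median -0.54, the stress median -0.50 and the iron median -1.61. Against BY4741 replicate 1 alone, which shares gcn4's title wording, the medians were -0.42 for iron (adjusted p = 0.0782), 0.26 for mitochondrial, -0.09 for cytosolic ribosomal protein (0.843) and 0.44 for one-carbon genes (0.0101). Against BY4741 replicate 3 alone, the ribosomal protein medians were 0.81 and 0.60.

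Camera called 8 of 41 lists for gcn4 minus BY4741 (5 negative, 3 positive), 0 with an estimated correlation, and fry called 1. Without BY4741 replicate 3, 3 lists were called. With a common median absolute deviation the cytosolic ribosomal protein median was -0.10 (adjusted p = 0.782), the purine median 0.23, and the one-carbon (0.54, 0.00514) and stress lists (0.62, 0.000262) were called. With the coding-length curve removed the cytosolic ribosomal protein call ended (0.04, 0.587). The mitochondrial median was 0.25 with that curve removed and 0.24 with a common median absolute deviation. Of 5353 genes, 0 passed limma's test (187 at an unadjusted p under 0.05, smallest adjusted p = 0.584). From the arrays of these strains alone 21 genes passed (19 negative, 2 positive), MMT1 and VEL1 being the positive ones. Adjusted over each reported list alone, 0 genes passed.

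Between shm2 and BY4741, one-carbon and purine genes lay higher in shm2. GCV1 stood at 5.57 ± 0.73, GCV3 at 2.73 ± 0.49 and MET6 at 1.95 ± 0.52, and the purine genes ADE1 at 2.38 ± 1.00 and GUA1, GMP synthase, at 2.01 ± 0.83. The largest differences were those of HXT17 (5.97), GCV1 and HSP32 (5.20) above and ATG7 (-5.30), HAL5 (-5.24) and GPH1 below BY4741. The one-carbon list had 12 of 19 genes higher (median 0.51, camera adjusted p = 0.000933) and adjusted p = 0.457 with an estimated correlation, and without centring its median was -0.11 (adjusted p = 0.000951). The list holds SHM2, absent from the shm2 strain, and with the deleted gene set missing the one-carbon median was 0.50 (adjusted p = 0.00169). The purine list had 12 of 13 higher (median 0.89, adjusted p = 0.00149) and adjusted p = 0.194 with an estimated correlation. Stress genes lay lower (median -1.004, adjusted p = 0.000201), with GPH1 at -5.00 ± 1.05 and DDR2 at -2.61 ± 0.58. Mitochondrial ribosomal protein genes (median -0.48, adjusted p = 0.00168) had adjusted p = 0.686 with an estimated correlation. The cytosolic ribosomal protein (median -0.04, mean -0.03, test positive, adjusted p = 0.495) and iron lists (median -0.10, adjusted p = 0.368) were not called.

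Against BY4741 replicate 3 alone, which shares shm2's title wording, the medians were 0.30 for one-carbon, 0.52 for purine, -0.87 for stress and -0.34 for mitochondrial ribosomal protein genes, and the iron (adjusted p = 0.00181) and cytosolic ribosomal protein lists (0.000213) were called. Without BY4741 replicate 3 the one-carbon and mitochondrial medians were 0.91 and -0.78. With a common median absolute deviation the one-carbon (0.0869) and stress (0.0575) calls ended. Without centring the purine, stress and mitochondrial medians were 0.27, -1.62 and -1.10, and with the coding-length curve removed the cytosolic one was 0.14. Camera called 8 of 41 lists (2 negative, 6 positive), 1 with an estimated correlation, and fry called 1. Of 5442 genes, 0 passed limma's test (206 at an unadjusted p under 0.05, smallest adjusted p = 1.00) and 0 passed under the other settings. Adjusted over the list alone, 2 one-carbon genes passed, and 0 over all genes.

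Genes of serine and glycine metabolism outside these lists were read on every array. SER33, a second phosphoglycerate dehydrogenase, was positive on all 8 arrays (0.23 to 1.17), and AGX1, alanine-glyoxylate aminotransferase, was negative on every array with a value (from -0.54 to -2.33). GLY1, threonine aldolase, stood at -1.10 and 0.0056 on the BY4741 arrays, at 1.53 and 1.43 in bas1, 1.02 and 1.14 in bas2, -1.18 in gcn4 and 0.26 in shm2. CHA1, serine deaminase, stood at -0.56 and -0.45 in BY4741, 0.32 on bas1 replicate 1, -0.49 and -3.34 in bas2, -1.47 in gcn4 and -0.19 in shm2. SER1, the phosphoserine aminotransferase, stood at 0.15 and -0.25 in BY4741, 0.57 and 0.80 in bas1, -0.38 and -0.42 in bas2, 0.84 in gcn4 and 0.64 in shm2. Of the deleted genes, BAS1 stood at -0.69 and -0.39 in bas1, PHO2 at -1.04 and -0.16 in bas2, SHM2 at -0.24 in shm2, where no transcript of it is left to measure, and GCN4 had no value in gcn4. Both channels of an array come from the same strain, so these ratios and those of the marker genes HIS3, LEU2, MET17 and URA3 test no deletion. URA3, which the parent lacks, so that no transcript of it is measured, stood at -1.90 and -1.21 in BY4741. It stood at 3.47 and 3.36 on the second bas1 and bas2 arrays.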

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

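The 9 tests of technical explanations below were chosen after the results were seen, and the list differences come from the camera tests fixed before the data were examined.

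Among the lists chosen for report, those whose glycine response differed between a deletion strain and BY4741 by the camera test are given here. Over all lists tested, camera called 22 for bas1, 22 for bas2, 22 for their mean, 8 for gcn4 and 8 for shm2. In bas1 minus BY4741 the list medians were 0.47 for one-carbon, 1.57 for purine, 0.99 for arginine, 1.14 for lysine, 1.15 for phosphate, 1.57 for zinc, 1.37 for iron, -0.63 for cytosolic ribosomal protein, -0.74 for mitochondrial ribosomal protein and 0.88 for ergosterol genes. In bas2 minus BY4741 they were 0.59 for purine, 0.76 for lysine, 0.88 for zinc, 0.83 for iron, -0.33 for cytosolic ribosomal protein, -0.59 for mitochondrial ribosomal protein, -0.65 for stress, 0.49 for ergosterol, 0.82 for mating response and 0.52 for a-specific genes. For the mean of bas1 and bas2 they were 1.02 for purine, 1.13 for lysine, 1.10 for phosphate, 1.14 for zinc, 1.17 for iron, -0.48 for cytosolic ribosomal protein, -0.58 for mitochondrial ribosomal protein, -0.56 for stress and 0.87 for ergosterol genes. In gcn4 minus BY4741 they were -0.87 for iron, 0.29 for cytosolic ribosomal protein and 0.47 for mitochondrial ribosomal protein genes. In shm2 minus BY4741 they were 0.51 for one-carbon, 0.89 for purine, -0.48 for mitochondrial ribosomal protein and -1.004 for stress genes. With an estimated correlation the bas1 differences of one-carbon (adjusted p = 0.398), iron (0.236), cytosolic (0.398) and mitochondrial ribosomal protein genes (0.200) were lost. So were those of bas2 for purine (adjusted p = 0.112), iron (0.146), cytosolic (0.757) and mitochondrial ribosomal protein genes (0.158), and those of the mean for iron (0.140), cytosolic (0.490) and mitochondrial ribosomal protein genes (0.135). All 3 reported differences of gcn4 were lost (iron adjusted p = 0.535, cytosolic 0.963, mitochondrial 0.777), and in shm2 those of one-carbon (0.457), purine (0.194) and mitochondrial ribosomal protein genes (0.686).

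Spots without a gene name, which no comparison uses, also held ratios: 50 of the 1637 with both values were at least 1 in size with 1 sign on both BY4741 arrays (45 negative, 5 positive), against 14.1 by chance. Among 11015 named spots the counts were 74 negative and 32 positive, against 26.2 by chance.

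GCV1, GCV3 and SHM2, chosen after their values were seen, stood at -1.47 or lower on each BY4741, bas2 and gcn4 array with a value and between -1.17 and 1.41 on the bas1 and shm2 arrays (SHM2, deleted in shm2, not read there), while the whole one-carbon list was not called in gcn4 (adjusted p = 0.0765) and had medians of -0.12 on BY4741 replicate 3 and -0.24 on shm2 (18 genes without SHM2). On bas1 replicate 1 and shm2 the stress list lay lower than in BY4741, by -0.76 and -1.004. That goes against compressed ratios there only if these strains share the parent's stress response, since a larger response could lie lower even when compressed. With a common median absolute deviation, which itself evens out compression, the shm2 difference was -0.67. That of both bas1 arrays was then 0.42 (camera adjusted p = 0.297), so compression stays open. The stress list was negative in bas1 (median -0.82, camera adjusted p = 2.43e-05) and in its median on every other array. That goes against a turned ratio on the bas1 arrays only if bas1 shares the stress response of the other strains. With a turned sign the purine list would differ from BY4741 by 0.11 (camera adjusted p = 0.856). ADE2, ADE3 and ADE4, picked after the turn, would then be negative on all 8 arrays. Over all genes, however, those with 1 sign on all arrays would fall from 219 to 100. The bas1 arrays correlated positively with the bas2 arrays of the same replicate number (r = 0.63 and 0.49), which a turn would reverse. They correlated negatively with BY4741 replicate 1 (-0.35 and -0.22) and gcn4 (-0.14 and -0.27). The values point both ways, and a turned ratio stays open. Parent RNA on bas2 replicate 1 is argued against as the whole source of the bas2 values, since the list stayed negative without that array (median -0.40, adjusted p = 0.0197), but the label of that array stays open. The spread of bas1 replicate 2 is argued against for bas1, since the one-carbon difference from BY4741 was 1.02 without it (adjusted p = 1.07e-05), although -0.04 without replicate 1 (adjusted p = 0.794), and a loss of the response without Bas1 or Shm2 stays open as an untested hypothesis.

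Cytosolic ribosomal protein genes, which are short, were positive in BY4741, gcn4, shm2 and bas2 (median 0.33, adjusted p = 2.00e-06; adjusted p = 0.508 with an estimated correlation; 0.03 and 0.64 on the bas2 arrays), and ratios correlated negatively with coding length on BY4741 replicate 1 (Spearman -0.249) and gcn4 (-0.395). With the coding-length curve removed the list stayed positive in BY4741 (0.53 from 0.68, adjusted p = 2.19e-12) and gcn4 (0.50 from 0.88, adjusted p = 5.88e-05), which argues against length as the whole cause. Before that removal these calls had adjusted p = 0.193 and adjusted p = 0.581 with an estimated correlation. On gcn4, 17 of these genes had a ratio within 0.003 of 1 on every spot, as with saturation of both channels. After centring such spots stand near 0.26 there (RPL3 at 0.26), below the list median of 0.88, so they did not raise it. With them set missing the median was 0.996 (camera adjusted p = 1.82e-12). Removing values below the median could hardly lower it, so that result decides nothing about the cause. Saturation of 1 channel and other technical trends with abundance stay open, since the channel signals were not used here, and so does a biological response to glycine, which was not tested.

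Iron and zinc genes were positive on the bas1 and bas2 arrays. Spots of genes with little or no transcript may run positive on these arrays: the genes specific to alpha cells, silent in an a strain such as BY4741, had a median of 1.04 on bas2 replicate 1 beside 0.99 for the iron list, and 0.85 beside 1.43 on bas1 replicate 1. On bas1 replicate 2 the median of the 2 alpha-specific genes with a value was 3.52 beside 2.23 for the iron list, with MF(ALPHA)1, named after its value was seen, at 6.89, above FIT2 at 4.81 and TIS11 at 3.60. Of the marker genes that the parent lacks, URA3 stood at 3.47 and 3.36 on the second bas1 and bas2 arrays and at -0.20 and -0.05 on the first. LEU2 stood at 0.07 and -0.09 on the second and at 0.83 and 0.33 on the first. MET17, without a value on the second, stood at -0.04 and -0.32 on the first. The drift stays open, for the a-specific and mating calls of bas2 as well, and so does a strain difference in metal uptake, which was not tested.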

How the results depend on the processing

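Leaving out bas1 replicate 2 and bas2 replicate 2 together, the coding-length curve, the block with that curve and array weights were chosen after seeing the data. So were spots near a ratio of 1 set missing, deleted genes set missing in their strain and turned bas1 signs. All other alternatives were fixed before. Array weights, robust eBayes, spots within 0.003 of a ratio of 1 or deleted genes set missing, genes with a value on at least 1 array per strain and the 6 shared extreme spots set missing kept every gene count at 0 and every list count within 1.5 times. The one-carbon, purine and cytosolic ribosomal protein calls of BY4741 and the stress and iron calls of bas2 held under 22 alternatives each, all run at the preset correlation. With an estimated correlation the cytosolic ribosomal protein call of BY4741 was lost (adjusted p = 0.193 with an estimated correlation). Of 16278 values of named genes under alternatives, 117 passed an adjusted p of 0.05. The number of arrays limits all tests, and the signal over background is unknown. Except where fewer arrays explain a wider or narrower spread, the cause was not tested.

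With an estimated correlation, camera called 6 lists in BY4741, 6 in bas1, 9 in bas2, 0 in gcn4, 1 in shm2, 5 for the mean of the strains, 6 for bas1 minus BY4741, 6 for bas2 minus BY4741, 6 for their mean, 0 for gcn4 minus BY4741 and 1 for shm2 minus BY4741. Fry called 2 in BY4741, 9 in bas2, 1 in gcn4, 1 in shm2, 8 for the mean of the strains, 3 for bas1 minus BY4741, 2 for bas2 minus BY4741, 3 for their mean, 1 for gcn4 minus BY4741 and 1 for shm2 minus BY4741. From the arrays of the strains compared alone, 2 genes passed in BY4741 and 21 in gcn4 minus BY4741. Without centring, 1 gene passed in bas1, 13 in gcn4 and 2 for the mean of the strains, and 14 lists were called for bas1 minus BY4741. With the spot of larger mean size left out, 1 gene passed for the mean of the strains. At a threshold of 0.10, 1 gene and 20 lists passed for that mean and 14 lists for shm2 minus BY4741. With genes on all 8 arrays, 8 lists were called in shm2 and 5 in gcn4 minus BY4741.

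With a common median absolute deviation, the iron median turned to -0.065 in bas1 minus BY4741 and to -0.17 for the mean of bas1 and bas2, the cytosolic ribosomal protein median turned to -0.10 in gcn4 minus BY4741, and 5 lists were called for shm2 minus BY4741. With the coding-length curve removed, 3 lists were called for gcn4 minus BY4741. Without bas1 replicate 2 and bas2 replicate 2 together, 2 genes passed in BY4741, 122 in gcn4, 97 for the mean of the strains and 21 in gcn4 minus BY4741.

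With the replicate block, 8 lists were called in shm2, and with the block and the coding-length curve 8 in shm2, 10 in bas1 minus BY4741 and 2 in gcn4 minus BY4741. The block follows the wording of the titles, and differences between replicates correlated across genes at r = 0.542 between bas1 and bas2, 0.0555 between BY4741 and bas1 and -0.0298 between BY4741 and bas2. Among the replicated strains only bas1 and bas2 therefore shared a replicate effect, and gcn4 and shm2, with 1 array each, could not be checked. The replicate numbers were not taken as pairs. The main fit holds no term for the effect that bas1 and bas2 share, so the errors of their mean may be too small.

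Leaving out 1 array at a time, or those 2 together, genes called ran from 0 to 2 in BY4741, 0 to 641 in bas1, 0 to 122 in gcn4, 0 to 97 for the mean of the strains, 0 to 493 in bas1 minus BY4741 and 0 to 21 in gcn4 minus BY4741. Lists called ran from 3 to 20 in bas1, 11 to 22 in bas2, 2 to 22 in bas1 minus BY4741, 7 to 20 in bas2 minus BY4741, 8 to 21 for the mean of bas1 and bas2 and 3 to 9 in gcn4 minus BY4741. The cytosolic ribosomal protein median of bas2 minus BY4741 ran from -0.62 to 0.049.

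With the sign of both bas1 arrays turned, the medians in bas1 were -0.71 for purine, -0.75 for lysine, -0.64 for phosphate, -1.28 for zinc, -1.99 for iron, -0.79 for ergosterol, 0.53 for mitochondrial ribosomal protein and 0.82 for stress genes. For bas1 minus BY4741, 13 lists were called, with medians of 0.11 for purine, -1.10 for lysine, -0.16 for phosphate, -1.30 for zinc, -2.35 for iron, -0.80 for ergosterol and 0.48 for mitochondrial ribosomal protein genes. For the mean of bas1 and bas2 against BY4741, 6 lists were called, with medians of 0.15 for purine, 0.13 for phosphate, -0.22 for lysine, -0.17 for zinc, -0.75 for iron, -0.029 for ergosterol, 0.21 for mitochondrial ribosomal protein and 0.44 for stress genes, and the purine call ended (adjusted p = 0.612). For the mean of the strains the medians were 0.18 for iron, 0.22 for zinc, -0.04 for ergosterol and -0.44 for purine genes, the last of which gained a call (adjusted p = 0.000487).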

Other observations

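The counts and list values of this part were read after the results were seen.

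Hexose transporter genes were shifted to negative ratios in BY4741 (14 of 14 negative, median -0.47, camera adjusted p = 0.00053; adjusted p = 0.263 with an estimated correlation; -0.92 and -0.12 on replicates 1 and 3) and gcn4 (12 of 12, median -1.50, adjusted p = 1.46e-05; adjusted p = 0.334 with an estimated correlation). HXT7, a high-affinity glucose transporter, was negative on all 8 arrays, from -0.58 to -2.38. Genes specific to alpha cells, silent in an a strain, had medians of -0.67 and 0.15 on BY4741 replicates 1 and 3 and -0.54 on gcn4. Whether a drift of silent genes adds to the hexose transporter shifts was not tested. Histone genes were shifted positive in BY4741 (10 of 10, median 1.04, adjusted p = 1.45e-05; adjusted p = 0.140 with an estimated correlation, and 1.71 and 0.28 on the arrays) and gcn4 (10 of 10, median 1.08, adjusted p = 0.00904; adjusted p = 0.632 with an estimated correlation). Respiratory chain genes were shifted negative in bas1 (23 of 27 negative, median -0.82, adjusted p = 8.95e-06; adjusted p = 0.0895 with an estimated correlation) and bas2 (29 of 30, median -0.63, adjusted p = 1.16e-06; adjusted p = 0.0673 with an estimated correlation), with -1.12 and -0.93 on the bas1 arrays and -0.95 and -0.47 on the bas2 arrays. The vitamin B6 genes of the SNZ and SNO families were shifted negative in BY4741 (6 of 6, median -0.79, adjusted p = 3.26e-05; adjusted p = 0.140 with an estimated correlation, and -1.16 and -0.53 on the arrays), with SNZ1 at -4.35 and -3.69 on the arrays.

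Of the 3168 genes with a value on every array, 219 had 1 sign on all 8 arrays (69 negative, 150 positive), against 24.75 by chance if arrays were independent. With the signs of both bas1 arrays turned the count was 100 (32 negative, 68 positive). These include ADE2, ADE3 and ADE4, negative on the other 6 arrays and positive on both bas1 arrays, while no gene of the 219 can be among them. The smallest p that an exact two-sided sign-flip test over 8 arrays can give is 0.00781. The positive genes included TIS11, the zinc transporter gene ZRT1, the peroxisomal citrate synthase gene CIT2 and SER3, with means over arrays of 2.43, 1.77, 1.58 and 1.43. The ZRT1 spots on gcn4 lay within 0.003 of a ratio of 1, so its sign there came from centring. The negative ones included the stress genes GAD1, PGM2 and TSL1, a trehalose synthesis gene, with means of -1.64, -1.28 and -1.28.

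On the single gcn4 array, the 5 lowest genes named had deposited ratios between 0.004 and 0.007, near the smallest step of the ratio scale (0.001), and on the shm2 array between 0.04 and 0.048.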
